A study of Homo sapiens with 10 samples.

How the data were processed

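Erythroblasts were grown from adult human CD34+ blood progenitor cells in a serum-free culture of 3 phases, per the labels' protocols. Cells received lentivirus on culture day 3, puromycin followed after 24 hours for 3 days, and 7 days in the second medium came next. Live cells were sorted on day 14. The knockdown group (4 libraries) received an shRNA against RIOK3, the same clone in each library. The control group (6 libraries) received a non-targeting shRNA. The labels number the libraries by donor, so replicates are separate cultures. Total RNA was depleted of globin RNA and of ribosomal RNA with commercial kits, and libraries were read as paired ends, per the labels' protocols. RNA of the globin genes can therefore measure the depletion as well as the cells.

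The 2 groups were processed differently before deposit. For the knockdown libraries the authors deposited whole-number read counts per gene symbol, in files with the category lines of HTSeq (26364 symbols each). For the controls the authors deposited tables of Cufflinks type with an FPKM, a 95% confidence range and a coverage for each of 41138 RefSeq transcripts of 23273 genes, per the file headers. The submitters' processing notes name CASAVA 1.8.2, STAR, HTSeq 0.6.1p1 and the build hg19 for every library; the aligner behind the control tables is not given in the sources used here. File type, and any library batch that went with it, coincides with the group, so no value within a batch and no fit with batch as a term can be had, and processing and shRNA cannot be told apart by design. The control labels point to earlier deposited records. The same numbers appear in both groups, but the labels and the names of the files do not pair them in the same way, so the numbers were not read as naming shared donors.

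The knockdown files listed 77147852 to 83939590 reads each. Of these, 31222138 to 35396084 were assigned to genes, 34.6 to 41.4% fell in no feature, 1.15 to 1.49% were ambiguous between genes and 18.0 to 21.7% did not align uniquely. These categories were left out of library sizes. The control tables state no depth. In 2.66 to 3.28% of knockdown gene counts the symbol was absent from the control tables (4997 symbols), and 1906 symbols were only in the control tables; the remaining 21367 were shared. Libraries of a group differed by far more than counting error, with a chi-square per degree of freedom of at least 21.4 in every pair, so none was treated as a repeat of another. A status other than OK was carried by 29 transcript rows of the controls.

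Both kinds of value were brought to TPM over shared genes. Knockdown counts were divided by the transcript length weighted by the control FPKM, control FPKM was summed per gene, and each library was scaled to TPM. Genes shorter than 300 bases, globin and mitochondrial genes, genes on the Y chromosome, XIST and TSIX were left out. Genes with a TPM of at least 1 in at least 4 libraries were kept (10272 genes), TMM factors were applied, and log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3 (limma-trend, treat with a minimum change of 1 on the log2 scale, Benjamini-Hochberg adjusted p under 0.05, two-sided). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Because 1 test covers all genes, adjusted p-values below are limma's unless another test is named. RIOK3 was also tested with an exact two-sided permutation test over all 210 splits. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, and the list median was placed among 10000 random lists matched on mean expression. Lists with fewer than 3 tested members had no test. Globin genes were given as values, over TPM that includes them.

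Designs, lists, the rule for named genes and the alternatives of the last paragraph were fixed before the data were examined. Named genes are RIOK3, the 12 largest falls and 12 largest rises among genes past the test whose groups do not overlap, with a mean TPM of at least 10 in the higher group, a value above 0 in at least 1 library of each group, at least 500 bases, a single locus and a symbol outside those of ribosomal, histone, small RNA and uncharacterised genes and not ending in AS1, P1 or P2; and, as examples, the members of each list with the largest changes past the test (up to 3 in each direction). A gene counts under each list that holds it, and SLC4A1, KIT and CA1 are in several. The globin list was given as values. The other lists cover erythroid identity, haem and iron, the membrane skeleton, late maturation, progenitors, fetal haemoglobin regulators, interferon response, RNA sensing, NF-κB targets, p53 targets, small-subunit maturation, ribosomal proteins, cell cycle, chromatin condensation, unfolded protein and stress, immediate early genes, glycolysis and hypoxia, apoptosis, and RIO kinases with caspase partners. Marker lists cover neutrophils, monocytes, megakaryocytes, mast cells with basophils and eosinophils, lymphoid cells, early erythroid progenitors and late erythroblasts.

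The control FPKM carried a weight that depends on base composition. For genes with 1 transcript the number of fragments behind an FPKM was recovered from its upper confidence limit as the square of 2 × FPKM / (upper limit − FPKM). Among numbers up to 10, between 91.2 and 92.3% lay within 0.05 of a whole number in each control library. FPKM times length per recovered fragment rose with GC content in all 6 libraries (Spearman 0.880 to 0.903 across genes, 0.912 to 0.931 among genes with at most 500 fragments), and was 1.79 to 2.50 higher on the log2 scale in genes above 60% GC than in genes up to 40%. GC content came from GENCODE 29 transcripts and was found for 94.1% of shared genes; genes are not independent replicates. Recovery failed for some abundant genes, whose confidence range was wider than counting error: SLC2A1 gave 2195 to 2248 fragments while its FPKM ran from 364 to 518. Genes whose FPKM per fragment lay over 0.5 (log2) above that of genes of like GC content (522 of 5051 judged) and genes without a GC value were therefore left out of every fragment-based value. RIOK3 lay at −0.02 on that scale and the late maturation list at a median of −0.06. The 20 ribosomal protein genes judged had a median of 0.40, and 7 of them were left out. If fragments were lost in recovery, this would lower their control fragments and raise their change. Genes were matched on GC content and not on length, so the cause of this excess was not tested. Recovered fragments of the genes kept were compared with knockdown counts as CPM in limma, and with edgeR 4.0.16 (glmTreat on rounded numbers). A loess adjustment of each library on GC content (span 0.5) and a fit to genes above 0 in every control table were further alternatives. These were chosen after seeing the data, and the removal of genes from the fragments after SLC2A1 had been seen to reverse on them.

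Whether same-numbered libraries deviate together was checked from the correlation of their deviations from the group means. Other alternatives were a pseudocount of 0.1, no filter or a TPM of at least 5, no scaling, quantile normalization, no minimum change or one of 2, the longest transcript, CPM from reads rebuilt as coverage times length (the deposited coverage is a signal per base), genes with 1 transcript of at least 1000 bases, library weights, robust empirical Bayes, a replicate block and leaving out each library. The scripts were tested on simulated data for this comparison: of 200 genes changed among 10272, the test called 90.0% of those changed by 2 and 98.0% of those changed by 3 on the log2 scale. With no change simulated it called 0 genes. The simulation did not include a difference in processing. Tables were prepared with Python 3.11.15, pandas 2.3.3 and bedtools 2.31.1.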

Results

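Messenger RNA was measured in 10 libraries of day 14 erythroblasts, the nucleated precursors of red blood cells, grown from adult CD34+ cells. In 4 libraries RIOK3, a gene of the RIO family of atypical kinases, had been targeted with an shRNA, and 6 libraries carried a non-targeting shRNA. Knockdown libraries held 31222138 to 35396084 gene counts each. The control tables held FPKM values with no depth stated. The comparison asks which genes differ between cells with the RIOK3 shRNA and cells with the non-targeting shRNA. All knockdown libraries carried the same shRNA clone, so lowered RIOK3 and other effects of that clone cannot be told apart. Knockdown files held counts and control files FPKM, so shRNA and processing cannot be told apart in any difference between the groups, and no value within a single kind of file can be had. Recovered fragments are the fragment numbers behind the control FPKM of genes with 1 transcript, which carry no weight by base composition; this scale was chosen after seeing the data.

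RIOK3 was lower in all 4 knockdown libraries than in any of the 6 controls. It lies on chromosome 18 at 21032787 to 21063099 (hg19). Its scaled TPM was 23.1 ± 1.22 (SD, n = 4) in the knockdown group and 252 ± 101 (SD, n = 6) in the control group, 9.16% of the control level. The change was −3.30 ± 0.25 (SE) on the log2 scale (exact two-sided permutation p = 0.00476, the smallest that 210 splits can give). On recovered fragments it was −4.04, and the remaining level was 5.65% of control. The groups did not overlap for 70.0% of all genes tested, so this p does not set RIOK3 apart. By size its fall ranked 322 among the 1569 falls eligible for naming. Whether less mature cells account for part of it cannot be told apart from the shRNA. Knockdown libraries held 1988 to 2347 RIOK3 counts each, and 8707 to 25128 fragments were recovered per control library. RIOK3 has 1 named pseudogene, with which reads can be shared.

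**Figure D1:**
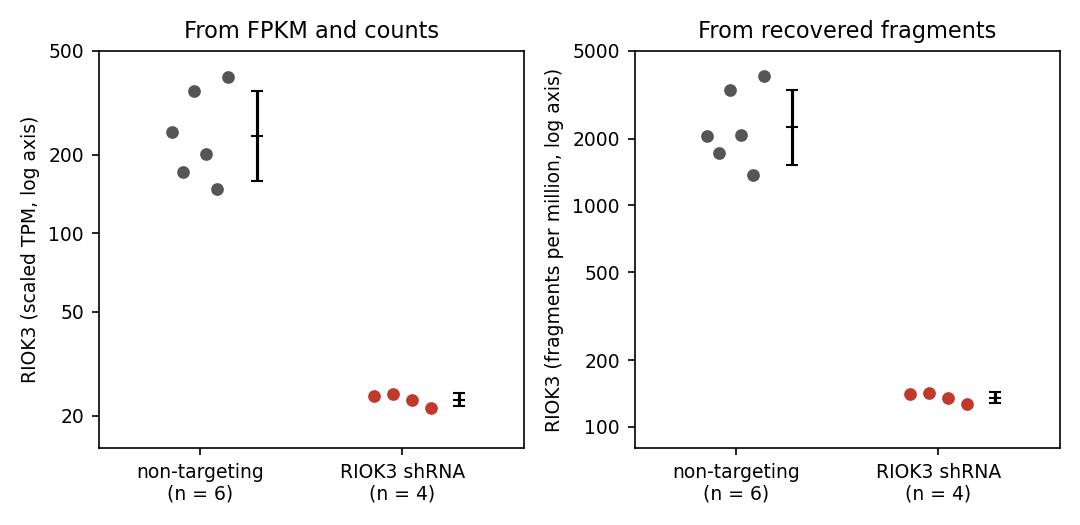
RIOK3 in each library on log axes, as scaled TPM (left) and as counts or recovered fragments scaled to CPM over genes with 1 transcript (right). Points are libraries, and the bar beside them is the mean ± SD of log2 values, shown back on the plotted scale. The 4 knockdown libraries, at 21.4 to 24.2 TPM, sit below the 6 controls, at 148 to 397 TPM.

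The late red-cell program was lower in the knockdown libraries. Of 24 late maturation genes tested, 19 fell, 0 rose and 5 did not pass the test (20 fell when adjusted over the list alone), with a list median of −3.14. ULK1, a kinase that starts autophagy, changed by −5.49. CA1, a carbonic anhydrase of red cells, changed by −5.15. BCL2L1, which encodes the survival protein BCL-XL, went from 681 ± 197 (SD, n = 6) to 6.90 ± 2.51 TPM (SD, n = 4), a change of −6.43, but 43.0% of its annotated exon bases overlap another gene, so its count is uncertain. The list passed camera (adjusted p = 3.93e-07; adjusted p = 0.391 with an estimated correlation) and its median lay below all 10000 random lists. On recovered fragments 10 of 12 members fell, with a median of −3.27.

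Erythroid identity genes were lower too, with 15 of 24 falling and 0 rising (15 adjusted over the list alone; median −1.95, camera adjusted p = 7.03e-05, adjusted p = 0.348 with an estimated correlation). SLC4A1, the anion exchanger band 3, went from 5510 ± 506 to 193 ± 39.0 TPM (SD, n = 6 and 4), a change of −4.84. RHCE, which carries Rh blood group antigens, changed by −4.78, and ZFPM1, a cofactor of GATA1, by −4.11. Neither has a recovered-fragment value. Copies were looked for as named pseudogenes only. Reads that RHCE may share with RHD, the other Rh gene of the list, were not checked, so the RHCE count is uncertain. On recovered fragments 6 of 11 identity genes fell and 0 rose. With the GC adjustment 14 of 24 fell and 1, LMO2, rose by 1.84 (limma). KLF1 and ABCB6, at −1.71 and −1.78 on TPM, lost their calls on both. KLF1 was at 0.12 on fragments and −0.32 with the adjustment. LMO2, KLF1 and ABCB6 were named after their values were seen. In the membrane skeleton list 14 of 23 genes fell and 0 rose (14 adjusted over the list alone; median −1.72, camera adjusted p = 1.65e-05, adjusted p = 0.391 with an estimated correlation); TMOD1, a tropomodulin, changed by −4.14, with 45.0% of its exon bases overlapping another gene. SLC2A1, the glucose transporter GLUT1, changed by −3.58, and has no usable recovered-fragment value. Late erythroblast markers fell in 8 of 9 cases (8 adjusted over the list alone; median −2.69, camera adjusted p = 0.000759, adjusted p = 0.391 with an estimated correlation), among them EPB42, which encodes protein 4.2, at −3.46, with 14.7% of its exon bases overlapping another gene. On recovered fragments the medians were −1.63 for erythroid identity, −1.65 for the membrane skeleton and −2.45 for late erythroblast markers.

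Haem and iron genes fell in 11 of 22 cases and 1 rose (the same numbers adjusted over the list alone), with a median of −1.49 and a camera adjusted p of 0.000257, which became an adjusted p of 0.391 with an estimated correlation. SLC25A39, which has 2 named pseudogenes, changed by −5.10 and the mitochondrial iron importer SLC25A37 by −3.30. FLVCR1, a haem exporter, rose by 2.34. On recovered fragments the list did not pass (median −0.80, camera adjusted p = 0.104, 10 genes). With the GC adjustment 7 of the 22 genes fell and 1 rose (limma), with a median of −0.63. The list then passed camera at the preset correlation (adjusted p = 0.00260) but not with an estimated one (adjusted p = 0.321).

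Immediate early genes and stress genes were lower on balance. Of 13 immediate early genes 11 fell and 0 rose (11 adjusted over the list alone; median −2.92, camera adjusted p = 0.000257, adjusted p = 0.391 with an estimated correlation). JUND, FOS and FOSB, which encode AP-1 subunits, changed by −5.97, −5.05 and −4.62. On recovered fragments 8 of 10 immediate early genes fell and 0 rose (median −2.38). With the GC adjustment 8 of 13 fell and 1, MYC, rose by 1.95 (limma, list median −1.96). JUN, JUNB and EGR1 lost their calls there, at −1.65, −1.31 and −1.96. MYC, JUN, JUNB and EGR1 were named after their values were seen. In the unfolded protein and stress list 9 of 19 genes fell and the chaperonin gene HSPD1, which has 17 named pseudogenes, rose, while DDIT3 passed the test only against listed values of 0 (2 higher and 9 lower in all, the same numbers adjusted over the list alone; median −1.32, camera adjusted p = 0.0302, adjusted p = 0.391 with an estimated correlation). TRIB3 and CHAC1, targets of the integrated stress response, changed by −7.07 and −5.23. DDIT3, another target of that response, had 30.0 ± 4.42 TPM (SD, n = 4) in the knockdown group and was listed at 0 in all 6 control tables, with 39.6% of its exon bases overlapping another gene, so no rise and no fold are given. A listed 0 can be a failed estimate: HSPE1, named after its values were seen, was at 0 in 4 control tables and at 117 to 170 TPM in the other 2. Among genes above 0 in every control table the list median was −1.84.

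Ribosome genes were higher on balance. Of 27 genes of small ribosomal subunit maturation 13 rose and 1 fell (the same numbers adjusted over the list alone; median 1.41, camera adjusted p = 0.000459, adjusted p = 0.391 with an estimated correlation). WDR3, with 17.1% of its exon bases overlapping another gene, rose from 4.07 ± 1.37 to 60.2 ± 7.65 TPM (SD, n = 6 and 4), RIOK2, a related kinase of 40S maturation, by 2.63 on the log2 scale, and NOP58 by 2.63. NOC4L fell by 2.01, a call that ended on recovered fragments, at −0.72, and with the GC adjustment, at −0.59. Of 29 ribosomal protein genes 16 rose and 1 fell, and 18 rose and 1 fell adjusted over the list alone (median 1.72, camera adjusted p = 8.57e-05, adjusted p = 0.428 with an estimated correlation). RPS7 and RPL6 rose by 4.19 and 3.91, and RPL8 fell by 2.20, a call that ended with the GC adjustment, at −0.82. All 29 have at least 1 named pseudogene and as many as 37, so their reads can be shared with copies. On recovered fragments the medians were 1.65 for small-subunit maturation and 2.23 for the 13 ribosomal protein genes left.

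Progenitor markers divided. KIT, the stem cell factor receptor, rose by 2.89, the transcription factor MYB by 2.85 and CNRIP1 by 2.76. The early erythroid progenitor list had 3 of 5 genes higher and the other 2 not past the test (3 adjusted over the list alone; median 2.76, camera adjusted p = 0.223). The wider progenitor list had 3 of 9 higher and 0 lower over all genes, and 3 higher and 1 lower adjusted over the list alone (median 0.24, camera adjusted p = 0.630). Of 9 mast cell, basophil and eosinophil markers 3 rose and 0 fell (3 adjusted over the list alone; median 1.57, camera adjusted p = 0.143), including CPA3, a mast cell protease, at 30.5 ± 9.91 TPM (SD, n = 4) against 1.95 ± 0.848 (SD, n = 6). On recovered fragments 5 of 6 of the mast cell, basophil and eosinophil markers rose (median 2.11, camera adjusted p = 0.0444, adjusted p = 0.313 with an estimated correlation). KIT belongs to all 3 of these lists, as does GATA2, named after its values were seen. GATA2 was at 2.63 TPM in the knockdown group against 7.72 in the controls. Its change of −1.19 did not pass the test, and with the GC adjustment it was 0.23. Markers of other blood cell types together held 0.0519 to 0.0703% of TPM in the knockdown libraries and 0.0146 to 0.0291% in the controls.

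Lists of innate immune signalling, in which RIOK3 is known to act, did not pass camera. In the interferon response list 4 of 23 genes fell and 1 rose (median −0.10, and 0.38 without scaling; camera adjusted p = 0.362; 4 fell and 0 rose adjusted over the list alone). RSAD2, an antiviral enzyme, changed by −3.86. IFI44 rose by 1.66, a call that ended on recovered fragments, at 1.43, and with the GC adjustment, at 0.80, while USP18, named after its values were seen, was at 1.29 on TPM and rose on both, by 1.83 and 1.72 (limma). In the RNA sensing list 4 of 18 fell and 1 rose, also adjusted over the list alone (median −0.32, and 0.01 without scaling; camera adjusted p = 0.257). With the GC adjustment none of these 5 calls stayed: IRF7, NLRX1 and IRF3 went from −2.29, −1.97 and −1.95 to −0.95, −0.57 and −0.57, ADAR from −1.47 to −1.28 and TBK1 from 1.63 to 0.74. The 1 gene that rose there (limma) was IKBKE, at 2.13 against 0.85 on TPM, and the 1 of 8 that fell on recovered fragments was IFIH1, at −1.44 against −0.65 on TPM. ADAR, TBK1, IKBKE and IFIH1 were named after their values were seen. Among NF-κB targets 3 of 13 fell and 1 rose, also adjusted over the list alone (median −0.47, and 0.07 with the GC adjustment; camera adjusted p = 0.281), with NFKB1 at 2.68. With the GC adjustment 2 of these 13 fell and 2 rose (limma), as RELA lost its call, at −1.42, and NFKBIE, named after its values were seen, rose by 1.74; on recovered fragments 0 of 9 changed. Of 6 tested RIO kinases and caspase partners 2 rose and 1, RIOK3 itself, fell, also adjusted over the list alone (median −0.52, camera adjusted p = 0.763); RIOK1 rose by 1.73, a call that ended with the GC adjustment, at 1.18.

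**Figure D2:**
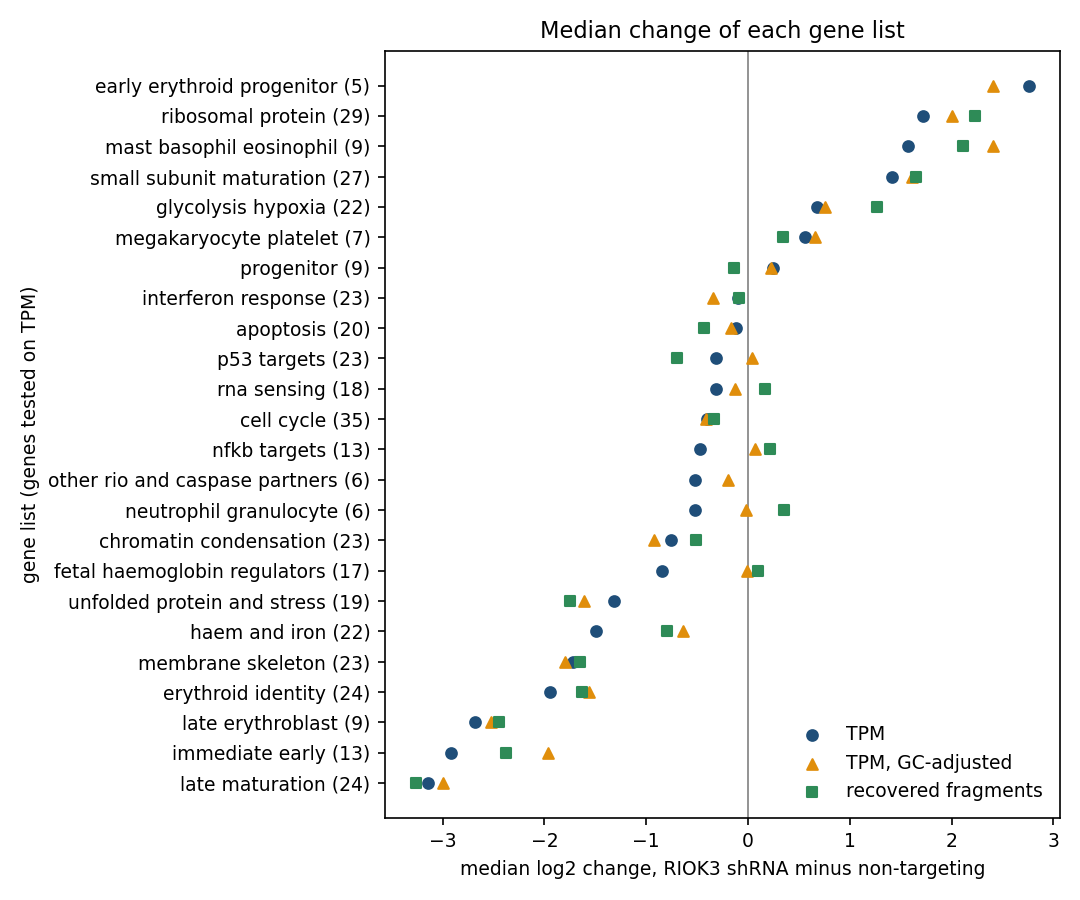
Median log2 change (horizontal axis, RIOK3 shRNA minus non-targeting shRNA) of each gene list (vertical axis, number of genes tested on TPM in brackets), on TPM, on TPM adjusted for GC content and on recovered fragments, which cover fewer genes. Late maturation is lowest on all 3 (−3.14, −3.00 and −3.27), and ribosomal protein genes are above 1.7 on each.

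Over all 10272 genes tested, 3720 changed, 1750 higher and 1970 lower in the knockdown group (limma, adjusted p under 0.05 for a change beyond 1). The higher ones include 211 of the 413 genes tested with a 0 in any control library, and 52 of the 413 reached 10 TPM in another control library, so these calls are uncertain. Without scaling the split was 2774 higher and 1330 lower, as the median change of all genes moved from 0.13 to 0.57. On recovered fragments 1679 of 5757 genes changed, 900 higher and 779 lower. The change fell with GC content across genes (Spearman −0.51 on TPM, −0.13 on recovered fragments). The groups did not overlap for 70.0% of genes, where chance gives 0.952%.

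**Figure D3:**
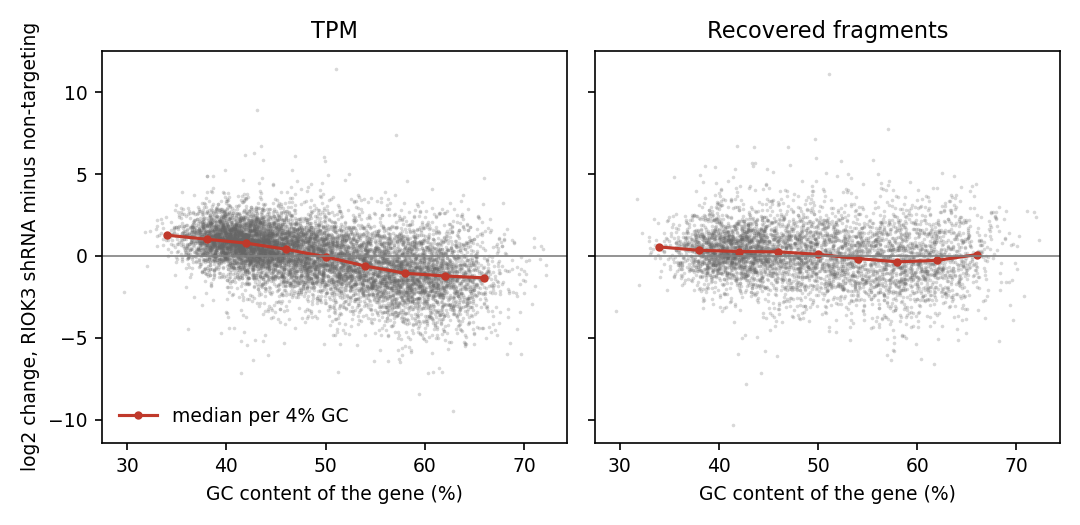
Log2 change of each gene (vertical axis, RIOK3 shRNA minus non-targeting shRNA) against its GC content in percent (horizontal axis), on TPM (left) and on recovered fragments (right). Each point is a gene and the line joins the medians of GC classes. Genes are not independent replicates. The slope seen on TPM (Spearman −0.51) is smaller on recovered fragments (−0.13).

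Among single genes the largest falls were TMCC2 (−8.40), SLC7A5, a large neutral amino acid transporter (−7.17), EGLN2, an oxygen sensor (−7.10), TRIB3 (−7.07), YPEL3 (−6.84), LRP10 (−6.44), BCL2L1 (−6.43), IFIT1B (−6.33), RNASEK (−6.26), TNS1, a focal adhesion protein (−6.04), PITX1 (−5.97) and JUND (−5.97). The limma adjusted p of these 12 was at most 2.34e-07. EGLN2 and RNASEK overlap readthrough genes and SLC7A5 has 2 named pseudogenes, so their counts are uncertain. Of the 12, the 7 with a recovered-fragment value also fell on it, SLC7A5 by 6.28 and IFIT1B by 7.81.

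The largest rises were SLC16A9, a monocarboxylate transporter family member (6.16), APOE, apolipoprotein E (4.78), NPM1, a nucleolar protein (4.62), FAM92A1 (4.27), FAM35A (4.20), CBWD5 (3.96), TUBB2B (3.93), EEF1A1, a translation elongation factor (3.91), and 4 genes listed at 0 in several control tables, where a 0 can be a failed estimate. SLC16A9 was at 121 ± 5.65 TPM (SD, n = 4) against 0.789 ± 0.671 (SD, n = 6), and APOE at 377 ± 95.5 against 14.3 ± 8.50. GLT8D1 and FAM216A, with 10.6 and 15.4% of exon bases overlapping another gene, were listed at 0 in 5 of 6 control tables, TMX2 and FABP5 in 4 of 6, and their knockdown means were 53.9, 30.9, 83.0 and 20.7 TPM. NPM1 has 45 named pseudogenes and EEF1A1 39, and FABP5, FAM92A1 and TUBB2B have copies as well. These counts are uncertain, as are those of CBWD5, from a family of close copies. FAM35A and FAM92A1 had no match in the gene annotation. Their exon overlap was therefore not checked, and the FAM35A count is uncertain too. TMX2 overlaps a readthrough gene, and its call (limma adjusted p = 0.0333) ended in 8 of the 10 fits that left out 1 library. SLC16A9 rose by 6.73 on recovered fragments.

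Globin RNA was depleted with a kit, and globin genes were read as values only. Which of these genes the kit removes was not examined. Nor were reads shared between similar ones, such as HBG1 and HBG2. HBB was at 5.79 ± 5.05 TPM (SD, n = 4) in the knockdown group and 1417 ± 322 (SD, n = 6) in the controls, HBG2 at 14.7 ± 5.60 and 12710 ± 6387, HBD at 0.155 ± 0.111 and 1024 ± 287, and HBM at 22.5 ± 6.54 and 5129 ± 2379. HBZ ranged from 6.55 to 10.7 TPM in the knockdown group and from 0 to 8.31 in the controls. No test across groups was made.

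Within each group, where all files share a type, the median coefficient of variation of TPM was 16.6% over 7325 genes in the knockdown group and 16.3% over 7420 genes in the controls. Across genes, Spearman correlations were 0.972 to 0.989 between knockdown libraries, 0.949 to 0.983 between controls and 0.632 to 0.726 between the groups.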

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

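Among 264 groups of values tested for a library far from the others, 12 had one (4.55%, where chance gives about 5%), and no explanation was tested for them. The gap between the far library and its nearest neighbour is given as a share of the group's whole range, which had to exceed Dixon's 95% critical value. Gene values are log2(TPM + 1).

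In the control group SLC16A9 was higher in replicate 4 than in the others (1.64 against 0.41 to 0.77, share 0.7034). GLT8D1 was listed above 0 in control replicate 5 alone (3.21, share 1), and FAM216A in control replicate 4 alone (2.43, share 1). RELA, an NF-κB subunit, was higher in control replicate 3 (5.41 against 4.84 to 5.02, share 0.6853), and HSPD1 was lower there (6.14 against 6.79 to 7.13, share 0.6543). RPL6 was lower in control replicate 3 (6.55 against 7.05 to 7.12, share 0.8779) and higher in knockdown replicate 2 (11.08 against 10.83 to 10.85, share 0.9258). BAD, a cell death gene, was higher in control replicate 5 (6.61 against 6.03 to 6.15, share 0.7899). PLK1, a mitotic kinase, was higher in knockdown replicate 4 (4.14 against 3.18 to 3.32, share 0.85). The score of the fetal haemoglobin regulators was higher in knockdown replicate 4 (−0.36 against −0.60 to −0.56, share 0.8411), and that of RNA sensing in control replicate 2 (0.23 against 0.15 to 0.18, share 0.6476). Reads that did not align uniquely made up 21.7% of knockdown replicate 3 and at most 18.5% of the other knockdown libraries (share 0.8712).

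In the knockdown libraries a mean of 2.899% of gene counts (2.66 to 3.28%) lay in symbols that the control tables do not hold, so no level in the controls can be set beside it.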

How the results depend on the processing

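The GC adjustment, the recovered fragments, the edgeR fit on them, their combinations and the fit to genes above 0 in every control table were chosen after seeing the data, as was the removal of 522 genes from the recovered fragments, which was made once SLC2A1 had been seen to reverse on them. The RIOK3 level kept its direction and its call in all 18 alternatives, from −2.82 without scaling to −4.04 on recovered fragments, and from −3.15 to −3.44 when 1 library was left out. The globin values and the spread within each group moved by less than the spread between replicates in every alternative run. Of the named genes none reversed where a value was kept: 2524 comparisons with an alternative kept direction and call and 148 lost the call. SLC2A1, a named example, is missing from the fragment comparisons because of that removal. Named genes without a value in an alternative were not compared there. The 2 libraries of number 1 deviated together (correlation across genes 0.39, above the 0.1 set as the lowest that pairs). Those of numbers 2, 3 and 4 did not (0.0020, −0.24 and −0.061). As 1 of 4 correlated best with its own number, the numbers were not read as pairs. Other pairings were not tested, so shared donors stay possible. With the number as a block RIOK3 was at −3.28 and 3408 genes changed. The total depth of the controls is not stated, and a 0 listed there can be a failed estimate, so no floor was set for such genes.

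The number of genes changed was 3084 to 3717 when 1 library was left out, and between these and 4390 with the pseudocount, filter, scaling, length, rebuilt reads, weights, robust and block alternatives. Among genes above 0 in every control table it was 3504 (1519 higher, 1985 lower), and no list changed its direction or its call. It went to 8327 (4436 higher, 3891 lower) with no minimum change and 1079 (340 higher, 739 lower) with a minimum of 2, which follows from the tests' construction. It was 2339 (1097 higher, 1242 lower) among genes with 1 transcript and 1000 bases, 1679 (900 higher, 779 lower) on recovered fragments, 1215 (640 higher, 575 lower) on those without overlap or copies, 1696 (962 higher, 734 lower) on those with the GC adjustment, 1492 (803 higher, 689 lower) on those with the block and 2245 (1204 higher, 1041 lower) with edgeR on them; these settings test fewer genes. With the GC adjustment 2706 changed, 1193 of them lower, and 1935 of 3587 calls were kept; with the block as well it was 2342, 965 of them lower. Without scaling 2774 were higher. For these 3 the cause was not tested.

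With an estimated correlation in camera none of the 9 lists past the test passed: erythroid identity −1.95 (adjusted p = 0.348), haem and iron −1.49, membrane skeleton −1.72, late maturation −3.14, small-subunit maturation 1.41, unfolded protein and stress −1.32, immediate early −2.92 and late erythroblast −2.69 (each adjusted p = 0.391) and ribosomal protein 1.72 (adjusted p = 0.428). Haem and iron also missed the threshold among genes with 1 transcript and 1000 bases (−1.15), on recovered fragments (−0.80), on those without overlap or copies (−0.62) and on those with the block (−0.88); these settings test fewer genes of the list. The other 8 passed camera at the preset correlation in every alternative run.

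With fry, which asks whether a list moves 1 way and compares it with no other genes, lists that missed camera passed: progenitor 0.24, fetal haemoglobin regulators −0.84, interferon response −0.10, RNA sensing −0.32, NF-κB targets −0.47, p53 targets −0.31, cell cycle −0.41, chromatin condensation −0.76, glycolysis and hypoxia 0.68, apoptosis −0.12, RIO kinases and caspase partners −0.52, neutrophil −0.52, mast cell, basophil and eosinophil 1.57 and early erythroid progenitor 2.76. At the preset correlation mast cell, basophil and eosinophil markers also passed camera with the GC adjustment (2.40) and on recovered fragments (2.11). They passed as well on fragments without overlap or copies (2.29), with the block and GC adjustment (2.27) and with the block on fragments (2.16). With an estimated correlation in camera they missed with the GC adjustment (adjusted p = 0.321) and on recovered fragments (adjusted p = 0.313). Cell cycle passed with the GC adjustment (−0.41) at the preset correlation, but not with an estimated one (camera adjusted p = 0.447). Chromatin condensation passed at the preset correlation on fragments without overlap or copies (−1.86), and early erythroid progenitor with the block and GC adjustment (2.27).

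Medians of lists that missed camera changed sign as follows, and the cause was not tested. On recovered fragments: progenitor −0.14, fetal haemoglobin regulators 0.10, RNA sensing 0.17, NF-κB targets 0.21 and neutrophil 0.35. On those without overlap or copies: the gene list progenitor −0.0021 and RNA sensing 0.20. With the block on fragments: fetal haemoglobin regulators 0.14, RNA sensing 0.17, NF-κB targets 0.26 and neutrophil 0.20. Without scaling: interferon response 0.38, RNA sensing 0.0087, p53 targets 0.16, cell cycle 0.089 and apoptosis 0.32. Among genes with 1 transcript and 1000 bases: interferon response 0.24 and apoptosis 0.16. With the GC adjustment: NF-κB targets 0.072 and p53 targets 0.035, and with the block as well 0.18, 0.20 and neutrophil 0.066. With CPM from rebuilt reads: neutrophil 0.14 and megakaryocyte −0.21. The interferon response ran from −0.22 to 0.070 when 1 library was left out, above 0 without knockdown replicate 1, 2 or 4 (0.070, 0.05 and 0.016). Apoptosis ran from −0.19 to 0.046, above 0 without control replicate 1, 2, 3 or 6 (0.040, 0.013, 0.017 and 0.046).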

Other observations

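Genes of the cell cycle, chromatin condensation and p53 lists moved both ways, and none of these lists passed camera on TPM. At the preset correlation cell cycle passed with the GC adjustment, and chromatin condensation on recovered fragments of genes without overlap or copies. With the GC adjustment and an estimated correlation cell cycle missed the threshold (camera adjusted p = 0.447). Of 35 cell cycle genes 8 were lower and 1 was higher, also adjusted over the list alone (median −0.41, and 0.09 without scaling; camera adjusted p = 0.0712). E2F2, a transcription factor of S phase, changed by −4.27, the mitotic kinase PLK1 by −3.64 and thymidylate synthase TYMS by −3.01, while CDK6 rose by 2.72. TYMS has 2 named pseudogenes, and 46.6% of its exon bases and 12.5% of those of PLK1 overlap another gene, so these counts are uncertain. Of 23 chromatin condensation genes 7 were lower and 3 higher, also adjusted over the list alone (median −0.76, camera adjusted p = 0.121), with the linker histone gene H1F0 at −5.45 and XPO7, a nuclear exporter, at −3.30. Of 23 p53 targets 6 were lower and 3 higher, also adjusted over the list alone (median −0.31, and 0.16 without scaling; camera adjusted p = 0.257), with SESN2 at −4.70, BTG2 at −4.45 and GDF15 at −4.22.

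Of 22 glycolysis and hypoxia genes 7 were higher and 6 lower, and 8 and 6 adjusted over the list alone (median 0.68, mean 0.06, with camera's direction down; camera adjusted p = 0.991). LDHB and PGK1, enzymes of glycolysis, rose by 2.67 and 2.43, while BPGM, which makes the regulator of haemoglobin's oxygen affinity, changed by −3.21. LDHB has 3 named pseudogenes and 33.4% of its exon bases overlap another gene, and PGK1 has 1 pseudogene, so the counts of LDHB and PGK1 are uncertain. Among 17 fetal haemoglobin regulators 7 were lower and 3 higher, also adjusted over the list alone (median −0.84, and 0.10 on recovered fragments; camera adjusted p = 0.257), with ZBTB7A at −3.21 and SOX6 at −2.57. Of 20 apoptosis genes 4 were higher and 3 lower, also adjusted over the list alone (median −0.12, and 0.32 without scaling; camera adjusted p = 0.702). Of 7 megakaryocyte genes 1 was higher, PPBP at 1.84, and 0 adjusted over the list alone (median 0.56, camera adjusted p = 0.718). PPBP lost its call on recovered fragments, at 1.40, and with the GC adjustment, while ITGA2B, named after its values were seen, passed on both, at 2.49 and 2.68. Of 6 neutrophil genes 0 changed, also adjusted over the list alone (limma; median −0.52, camera adjusted p = 0.60). Of the monocyte list 2 genes were tested, too few for a test, and of the lymphoid list 0.

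The tests of base composition, of dilution by other cells and of less mature cells, and the repeat of the pseudogene test with the GC adjustment, were chosen after the results were seen; the tests of other splits, overlap, the marker share of other cell types, pseudogenes and the relation within controls were written before. The number of changed genes lay beyond chance splits: 1 of 100 splits of the 10 libraries, the real one with 3720, gave as many, and the highest other gave 3. The split by group is also the split by kind of file.

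The lower level of late maturation genes does not follow from base composition, as their median on recovered fragments was −3.27 (SE 0.43, 12 genes). Nor does it follow from overlap or copies, as the 17 members without these had a median of −3.30 (SE 0.37). The SE of list medians here and in the next paragraph treats genes as independent. Estimated correlations on recovered fragments were 0.535 between late maturation genes and 0.695 between ribosomal protein genes. Such an SE does not measure the spread between libraries. Dilution by other blood cells would lower all erythroid genes alike. On recovered fragments the median of 10 erythroid identity genes lay 1.84 (SE 0.64) above that of the late maturation genes. This goes against dilution as the whole cause. Markers of other blood cell types held at most 0.0703% of TPM in a knockdown library (mean 0.0608%, against 0.0193% in the controls), led by PRG2, with 43.0% of its exon bases overlapping another gene, at a mean of 334 TPM and KIT, also a marker of early erythroid cells, at 71.1; this is under the 1% set beforehand, a bound not derived from these data, and the live gate would not remove such cells. A small share of such cells, other differences in processing or batch and an effect of the shRNA stay open; the last pair cannot be told apart, since both coincide with the group.

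The higher level of ribosomal protein genes does not follow from base composition, as the median of 13 genes on recovered fragments was 2.23 (SE 0.22), beyond the excess of 0.5 above which genes were left out. Whether reads shared with pseudogenes account for it cannot be told apart: the 3 genes with at most 1 named pseudogene had a median of 0.29, under the 0.5 set beforehand, but its SE was 1.61. With the GC adjustment the same 3 had a median of 1.52 (SE 1.23), with RPS25 at 2.50, RPS9 at 1.52 and RPL8 at −0.82, and RPS9, the only one of them with a recovered-fragment value, rose by 1.49 on that scale (limma); RPS25 and RPS9 were named after their values were seen. These values go against the explanation, but 3 genes decide nothing. The rule that such a value must lie beyond 2 SE to count for the explanation was set after it was seen. The other 26 genes had a median of 1.76, and the change rose with the number of pseudogenes across genes (Spearman 0.49). With the GC adjustment that median was 2.04 and the Spearman correlation 0.375. How the control tables treated multiple alignments is not known, so this explanation and the shRNA stay open.

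The lower RIOK3 level does not follow from base composition, as its change on recovered fragments was −4.04 (SE 0.24). Whether less mature cells in the knockdown cultures account for it cannot be told apart from the shRNA, which is aimed at RIOK3, since both coincide with the group. The share of late maturation genes that fell as much on recovered fragments was 2 of 12 (16.7%), above the mark of 1 in 20 set for less mature cells. It decides nothing, because 1 such gene of 12 would already pass that mark. On TPM RIOK3 changed by −3.30, near the late maturation median of −3.14.

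A hypothesis tested within the controls, where all files share a type, is that RIOK3 follows the maturation of the culture. Over the 6 control libraries RIOK3 correlated with the score of the 24 late maturation genes (Pearson r = 0.961, two-sided exact permutation p = 0.00556; Spearman rho = 0.886, two-sided exact permutation p = 0.0333). Without the 2 libraries farthest from the median r was 0.820, and on recovered fragments it was 0.956 with 12 genes in the score. Of the other tested genes 0.664% had an r as high. This was the only relation of its kind computed with a p, so no adjustment was made, and a cause shared by RIOK3 and the score, such as how far each culture had matured, is not told apart from others by it.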
